A study of Mus musculus with 12 samples.

How the data were processed

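Liver RNA of wild-type mice was profiled by RNA sequencing 9 days after the animals received 1 of 4 adenoviruses, per the labels' protocols. The 12 libraries fell into 4 groups of 3: Ad_GFP (a control virus carrying green fluorescent protein), ANG8 (a virus to raise ANGPTL8), shCtrl (a virus carrying a control short hairpin RNA) and shANG8 (a virus carrying a hairpin against Angptl8). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name CASAVA 1.8.2, featureCounts 1.5.0-p3 and the build mm9. The aligner, the strand setting of the counting and the annotation release are not given in the sources used here.

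The deposited table holds raw counts, whole numbers of reads per gene and library that were not normalized, for 54532 genes. The gene identifiers of 54495 of these genes are in GENCODE vM21, an annotation of the build GRCm38, and 53585 of them (98.3%) have identical coordinates there. Coordinates are therefore given as GRCm38 positions from the deposited table, although the submitters' processing notes name mm9. The table holds 12 count columns, 1 for each library. Total counts ranged from 12537083 to 15144312 per library.

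Every test was run on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which kept 14686 genes that held 99.9% of the counts in the library with the lowest share. Library sizes were scaled by the trimmed mean of M values (TMM). A negative binomial model with a robust quasi-likelihood fit was applied to all 12 libraries, so that the 4 groups shared the estimate of the spread. Each effect is a log2 fold change with a standard error (SE) taken as its absolute size divided by the square root of the F statistic. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. The comparisons were ANG8 minus Ad_GFP (overexpression), shANG8 minus shCtrl (knockdown), the difference between these effects, their sum, and shCtrl minus Ad_GFP. Levels are TMM-scaled CPM values with the standard deviation (SD) over 3 libraries, unless raw totals are named. The log2 CPM values of the principal component analysis used a prior count of 2.

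The precision that this depth and group size give was tested on simulated data drawn from the means and library sizes of the real libraries. In the overexpression comparison, with 14337 simulated genes tested, 4.48% of 67 genes changed by 1.5-fold were recovered, as were 40.3% of 67 genes changed by 2-fold and 83.3% of 66 genes changed by 4-fold, with 7 false calls. In the knockdown comparison, with 14327 simulated genes tested, the shares were 2.99%, 40.3% and 89.4%, with 4 false calls. The changed genes were drawn from those above a low level and were far fewer than the 1978 called under overexpression. Fewer changed genes make the adjustment stricter, so these shares are not the recovery of the real overexpression comparison. Each gene had the same mean in all unchanged groups, so both draws repeat the same setting and describe neither arm. In further simulated data for the lists, with 14351 genes tested for overexpression and 14325 for knockdown, camera called the list raised as a group and 0 of 30 random lists in each. The simulated genes were drawn independently of each other. These lists therefore do not show how often camera calls unchanged lists of correlated genes.

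The 34 gene lists covered lipid and glucose metabolism, bile acids, immune signalling, cell types of the liver, liver zones, sex-biased genes, stress responses, growth, the circadian clock, mitochondria, ribosomes and tissues that could contaminate liver. All but 3 of their symbols were found in the table. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, then with an estimated correlation and with fry, each adjusted over the 34 lists. Camera compares a list with the other genes. Fry asks whether the members of a list move, on balance, to 1 side, and compares no list with other genes. Members called were counted by the adjustment over all genes and adjusted over the list alone.

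The groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A few genes that this rule would name are not reported here. Named genes were Angptl8, and in each ANGPTL8 comparison the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1, with no overlap between the 3 libraries of each group and without a predicted-gene symbol. The rule added up to 4 members of each list with the smallest p, the 5 smallest p of the difference and of the sum, and up to 5 genes called in both comparisons for each pair of directions. Which of the list members serve as examples was chosen after their values were seen. Cd226 and Gm3788 are outside the rule and were also chosen after their values were seen.

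A gene was taken to have a near-identical copy when BLAST 2.17.0 aligned its transcript to that of another gene at 95% identity or more over at least 100 bases. The match may cover only a part of the transcript, so such a gene is not shown to have a copy of its whole length. Counts of such genes depend on how the counting step treated reads that match several places, and they are reported as uncertain. The alternatives were DESeq2 size factors and upper quartile normalization in edgeR, no filter on low counts, a filter of 50 counts in 3 libraries, the Wald test of DESeq2 1.42.0, limma voom with quality weights, a fit on the compared groups alone, the replicate number as a block, and leaving out each library in turn. The share of mitochondrial reads as a covariate, the removal of mitochondrial genes, and a fit restricted to protein-coding genes without a near-identical copy were added after the data were seen, as was the tally of called genes that are near-identical copies of ribosomal protein genes.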

Results

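RNA sequencing counts were collected from the livers of wild-type, chow-fed mice 9 days after an adenovirus was given, in a study of ANGPTL8 and lipid metabolism. ANGPTL8 is a secreted protein made by liver and adipose tissue after feeding that takes part in inhibiting lipoprotein lipase. The 4 groups held 3 libraries each: Ad_GFP and ANG8 form the overexpression arm, and shCtrl and shANG8 form the knockdown arm. Libraries held 12537083 to 15144312 counts, and 14686 genes were tested. The labels do not say that the libraries come from separate mice, so the p-values measure the spread between these samples, which may in part be technical. Replicates of each group differed by more than counting noise, with a chi-square per gene of 13.9 to 145 between libraries of 1 group. The leading principal component held 37.2% of the variance and set the ANG8 libraries (65.1 to 70.5) apart from the other libraries (-51.6 to 10.6). Mitochondrial genes took 27.1% ± 7.57 (SD, n = 3) of the counts in Ad_GFP, 35.1% ± 11.2 in ANG8, 23.5% ± 0.681 in shCtrl and 21.6% ± 2.0 in shANG8. Within ANG8 the libraries held 39.0%, 43.8% and 22.5%. An exact two-sided permutation test gave p = 0.3 for ANG8 against Ad_GFP and p = 0.2 for shANG8 against shCtrl, where 0.1 is the smallest p that 3 against 3 allows.

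To examine the targeted gene, Angptl8 (ENSMUSG00000047822, protein-coding, GRCm38 chromosome 9, 21835510 to 21837347, plus strand) was read in every library. Its level was 96.8, 80.4 and 90.0 CPM in the Ad_GFP libraries and 165, 314 and 172 CPM in the ANG8 libraries, a rise of 1.28 in log2 fold change (SE 0.33, edgeR adjusted p = 0.0201). The labels do not say whether the ANG8 virus carries the mouse or the human gene, so these counts may not measure the transgene. The level was 340, 391 and 167 CPM in the shCtrl libraries and 144, 143 and 79.2 CPM in the shANG8 libraries. Each shANG8 library lay below each shCtrl library, but the log2 fold change of -1.29 (SE 0.33) did not pass the test (adjusted p = 0.235). Its size and SE were close to those under overexpression. The adjusted p also depends on the other genes of a comparison, with 28 called under knockdown and 1978 under overexpression. The adjusted values therefore do not show weaker evidence for the lower level under knockdown than for the rise. The effects of both viruses on Angptl8 differed by 2.58 (SE 0.46, adjusted p = 0.0070), and their sum was -0.01 (adjusted p = 0.994). Mean levels were 89.1 ± 8.24 CPM (SD, n = 3) in Ad_GFP, 217 ± 84.0 in ANG8, 299 ± 117 in shCtrl and 122 ± 37.1 in shANG8. The shCtrl level thus lay above that of ANG8, and shCtrl minus Ad_GFP was 1.75 (SE 0.33, adjusted p = 0.338). That difference passed in 5 of 17 alternatives: DESeq2 (adjusted p = 0.000283), voom (0.0105), no filter on low counts (1.16e-12), the replicate block (0.00748) and without shCtrl replicate 3 (0.0446), and the highest adjusted p was 0.887. The overexpression call was lost without Ad_GFP replicate 1 (adjusted p = 0.0598), Ad_GFP replicate 2 (0.0786), Ad_GFP replicate 3 (0.0538) or ANG8 replicate 2 (0.0732) and with the mitochondrial share as a covariate (0.0973), within a range of 6.37e-08 to 0.0973 over all alternatives. The knockdown of Angptl8 passed with DESeq2 (adjusted p = 0.00936), without the filter on low counts (1.87e-07), with the replicate number as a block (0.00666) and without shCtrl replicate 3 (0.0335), and the highest adjusted p among its alternatives was 0.592.

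**Figure D1:**
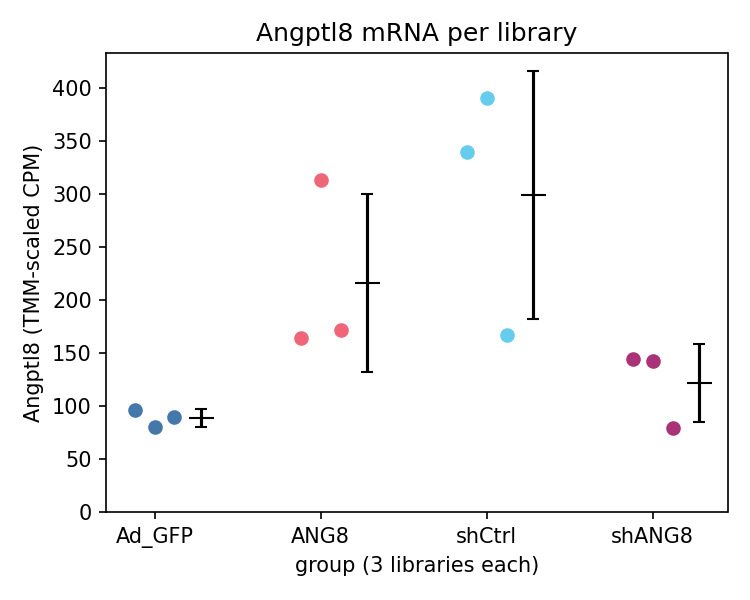
Angptl8 mRNA in TMM-scaled CPM (vertical axis, from 0) for each library of the 4 groups (horizontal axis); points are libraries, and the dash with bars is the mean ± SD of 3 libraries. The ANG8 libraries lie at 165, 314 and 172 CPM against 80.4 to 96.8 in Ad_GFP, and the shANG8 libraries lie at 144, 143 and 79.2 CPM against 340, 391 and 167 in shCtrl.

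The overexpression comparison asked which liver transcripts differ between ANG8 and Ad_GFP. Camera called lists of fat synthesis, glucose handling, hepatocyte and male-biased genes down and lists of interferon, T and NK cell, macrophage and cell cycle genes up. Of these, the fat synthesis list alone also passed with an estimated correlation between genes. The largest rise among named genes was that of Abcc4, an efflux transporter of bile acids and cyclic nucleotides (ENSMUSG00000032849, chromosome 14, 118482692 to 118706219), from 0.839 to 16.6 CPM (log2 fold change 4.31, SE 0.44, n = 3 and 3, adjusted p = 4.39e-05). Srxn1, which encodes the antioxidant enzyme sulfiredoxin, rose from 104 to 904 CPM (3.11, SE 0.39, adjusted p = 0.000398). Igfbp2, which encodes a binding protein of insulin-like growth factors, fell from 59.7 to 3.61 CPM (log2 fold change -4.06, SE 0.75, adjusted p = 0.00914). Other large rises were those of Slc1a4, a neutral amino acid transporter (3.03), Pdcd1, the checkpoint receptor PD-1 (2.71), Ksr2, a scaffold of MAP kinase signalling (2.68), Ccl24, an eosinophil chemokine (2.50), and Pdgfc, a platelet-derived growth factor (2.47). In all, 1978 of 14686 genes changed, 1040 up and 938 down, and 1119 of them changed by at least 2-fold (688 up and 431 down). The count moved by over 1.5 times without ANG8 replicate 1 (995 genes), ANG8 replicate 2 (1307), Ad_GFP replicate 1 (1080) or Ad_GFP replicate 2 (1133), and with limma voom (4181). Of the 101 named genes called under overexpression, 86 were called under every alternative that tested them, and Igfbp2 did not pass with the mitochondrial share as a covariate (adjusted p = 0.0741, the highest over its alternatives).

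Genes of de novo lipogenesis, the synthesis of fatty acids from carbohydrate, fell under the ANG8 virus: 16 of 23 tested members fell and 7 did not pass (19 fell when adjusted over the list alone). The list's median log2 fold change was -1.24, with a camera adjusted p of 1.24e-17 and an adjusted p of 0.0241 with an estimated correlation. Pklr, the liver pyruvate kinase, fell from 143 to 27.1 CPM (log2 fold change -2.40, SE 0.27, adjusted p = 7.61e-05), and Fasn, the fatty acid synthase, fell from 899 to 260 CPM (-1.79, SE 0.21, adjusted p = 9.66e-05). Acly, which makes cytosolic acetyl-CoA from citrate, fell by 1.84 on the log2 scale (SE 0.23), and Acacb, an acetyl-CoA carboxylase, fell by 1.30 (SE 0.17). Of 28 genes of glucose metabolism and insulin signalling, 15 fell and 13 did not pass (18 fell when adjusted over the list alone). The list median was -0.98 (camera adjusted p = 5.35e-09, adjusted p = 0.0665 with an estimated correlation). These included the liver glycogen synthase Gys2 (-1.33, SE 0.20), the liver glycogen phosphorylase Pygl (-1.17, SE 0.18) and the glucose transporter Slc2a2 (-1.05, SE 0.18). Of 25 genes of cholesterol synthesis and SREBP2 targets, 7 fell (9 when adjusted over the list alone). For this list the median was -0.47 (camera adjusted p = 4.66e-05, adjusted p = 0.411 with an estimated correlation).

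Other lipid lists moved less evenly. Of 34 lipoprotein genes, 4 rose and 11 fell (4 and 12 when adjusted over the list alone). As a list they had a median of -0.38 (camera adjusted p = 0.00126, adjusted p = 0.182 with an estimated correlation). Lipc, the hepatic lipase, fell (log2 fold change -1.89, SE 0.18, adjusted p = 4.39e-05), while Abcg1, a cholesterol exporter of macrophages and other cells, rose (1.98, SE 0.27, adjusted p = 0.000265). Lpl, the lipoprotein lipase that ANGPTL8 helps to inhibit, rose from 75.9 to 248 CPM (1.71, SE 0.21, adjusted p = 0.000138). This value is marked uncertain because at least a part of its transcript matched another gene by the rule for near-identical copies. Of 24 bile acid genes, 2 rose and 8 fell (2 and 9 when adjusted over the list alone). The list median was -0.54 (camera adjusted p = 0.000371, adjusted p = 0.0608 with an estimated correlation). Among these were the bile acid uptake carrier Slc10a1 (-2.14, SE 0.22), the bile acid CoA ligase Slc27a5 (-1.44, SE 0.21) and the sterol 12-alpha-hydroxylase Cyp8b1 (-1.65, SE 0.31). Fatty acid oxidation and PPAR-alpha targets did not pass as a list: 1 of 40 members rose and 7 fell (1 and 9 when adjusted over the list alone; median -0.16, camera adjusted p = 0.0623). The uncoupling protein gene Ucp2 rose (1.40, SE 0.23). Triglyceride synthesis and lipid droplet genes did not pass as a list either, with 1 of 26 up and 3 down (1 and 4 when adjusted over the list alone; median -0.17, camera adjusted p = 0.209).

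Of the immune lists, camera called those of interferon, T and NK cells, macrophages, NF-kB and dendritic cells up under the ANG8 virus. Of 37 interferon-stimulated genes, 20 rose and 17 did not pass (28 rose when adjusted over the list alone). For this list the median was 0.68 (camera adjusted p = 2.14e-13, adjusted p = 0.0665 with an estimated correlation). Examples were Ifi44 (1.22, SE 0.19), the nucleic acid sensor Zbp1 (1.14, SE 0.20) and the transcription factor Irf7 (0.93, SE 0.17). Of 30 T cell and NK cell genes, 13 rose and 1 fell (18 and 1 when adjusted over the list alone). As a list they had a median of 1.05 (camera adjusted p = 1.61e-09, adjusted p = 0.0608 with an estimated correlation). Cd8a, the alpha chain of the CD8 co-receptor, rose from 11.8 to 34.4 CPM (log2 fold change 1.54, SE 0.19, adjusted p = 0.000111). So did the NK receptor Klrk1 (1.47, SE 0.23), the T cell kinase Lck (1.30, SE 0.21) and the cytotoxic protease Gzma (1.82, SE 0.35). Of 25 macrophage and Kupffer cell markers, 17 rose and 8 did not pass (21 rose when adjusted over the list alone). The list median was 1.03 (camera adjusted p = 1.21e-15, adjusted p = 0.0665 with an estimated correlation). They included Aif1 (1.86, SE 0.20), the macrophage-secreted Cd5l (1.65, SE 0.24) and the transcription factor Spic (1.59, SE 0.29). Of 25 NF-kB and cytokine genes, 5 rose (11 when adjusted over the list alone), among them the chemokines Ccl3 (2.06, SE 0.37) and Ccl4 (1.84, SE 0.30). For this list the median was 0.48 (camera adjusted p = 0.000187, adjusted p = 0.0608 with an estimated correlation). Of 13 dendritic cell markers, 5 rose (7 when adjusted over the list alone), among them Cd74 (2.08, SE 0.35) and H2-Aa (1.54, SE 0.31) of MHC class II presentation. As a list they had a median of 0.84 (camera adjusted p = 0.000108, adjusted p = 0.108 with an estimated correlation).

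Camera also called the cell cycle, p53 and NRF2 lists up. Of 35 cell cycle genes, 22 rose and 13 did not pass (29 rose when adjusted over the list alone). The list median was 1.51 (camera adjusted p = 1.24e-17, adjusted p = 0.113 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose (1.98, SE 0.27), as did Ccne1, the cyclin of S phase entry (2.16, SE 0.30). Of 23 p53 target and cell death genes, 7 rose (13 when adjusted over the list alone), with Ccng1 (1.02, SE 0.16) and Casp1 (1.35, SE 0.25) as examples, a median of 0.69 and a camera adjusted p of 2.7e-06 (adjusted p = 0.0608 with an estimated correlation). Of 22 NRF2 target genes, which serve antioxidant defence, 8 rose and 1 fell (13 and 2 when adjusted over the list alone). For this list the median was 0.83 (camera adjusted p = 3.68e-07, adjusted p = 0.140 with an estimated correlation). Glutathione reductase Gsr (1.48, SE 0.18), the glutathione synthesis gene Gclc (2.13, SE 0.30) and thioredoxin reductase Txnrd1 (1.30, SE 0.19) were among them. The unfolded protein and integrated stress response list did not pass, with 3 of 27 up and 2 down by either adjustment, over all genes or adjusted over the list alone (median 0.06, camera adjusted p = 0.476).

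Camera called the hepatocyte, periportal, pericentral and male-biased lists down. Of 20 hepatocyte markers, 12 fell and 8 did not pass (1 rose and 14 fell when adjusted over the list alone). As a list they had a median of -0.96 (camera adjusted p = 1.25e-12, adjusted p = 0.0857 with an estimated correlation). Hpd and Uox, enzymes of tyrosine and urate breakdown, fell by 1.68 (SE 0.20) and by 1.43 (SE 0.21) on the log2 scale. Among 18 periportal genes, which mark hepatocytes near the portal vein, 1 rose and 11 fell (1 and 13 when adjusted over the list alone; median -0.95, camera adjusted p = 2.99e-08, adjusted p = 0.0780 with an estimated correlation). These included Gls2 (-1.56, SE 0.22), Hal (-1.77, SE 0.26) and the urea cycle enzyme gene Cps1 (-1.17, SE 0.22). Among 18 pericentral genes, 5 fell (1 rose and 5 fell when adjusted over the list alone), with Cyp2c29 as an example (-1.29, SE 0.20), a median of -0.32 and a camera adjusted p of 0.00593 (adjusted p = 0.177 with an estimated correlation). Male-biased liver genes held the lowest list median, -1.42, with 13 of 21 down (19 when adjusted over the list alone; camera adjusted p = 2.5e-12, adjusted p = 0.0665 with an estimated correlation). Examples were the organic anion carrier Slco1a1 (-2.45, SE 0.44) and the complement gene C8a (-1.44, SE 0.30). The major urinary proteins Mup1, Mup11, Mup12, Mup16 and Mup19 were among the named falls, at -3.61, -4.06, -5.22, -6.30 and -3.37, but each has near-identical copies and is uncertain. Mup1 and Mup11 each passed in 9 of 16 alternatives and Mup12 in 8, with a highest adjusted p of 0.141 for Mup1 (voom), and of 0.148 for Mup11 and 0.303 for Mup12 (both with the mitochondrial share as a covariate). Female-biased genes did not pass as a list, with 1 of 13 down (1 up and 4 down when adjusted over the list alone), a median of 0.27, a mean of -0.18 and a camera test that pointed down (adjusted p = 0.781).

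The other lists were of cell types, rhythms and housekeeping. Of 29 stellate cell and matrix genes, 3 rose (3 when adjusted over the list alone), among them Tgfb1 (1.09, SE 0.24) and Vim (1.24, SE 0.27), with a list median of 0.50 (camera adjusted p = 0.0205, adjusted p = 0.630 with an estimated correlation). EdgeR called 0 of 18 endothelial genes (0 also when adjusted over the list alone, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 3 by voom), with a median of 0.20 and a camera adjusted p of 0.315. The mean change of the macrophage list exceeded that of the endothelial list by 0.931 (SE 0.0979). EdgeR also called 0 members of the B and plasma cell (13 tested), cholangiocyte (7 tested) and neutrophil lists (5 tested), and 0 of each when adjusted over the list alone. At an unadjusted p under 0.05 they had 0, 3 and 0 members, DESeq2 called 0, 1 and 0, and voom 1, 2 and 0. Their medians were -0.12 (camera adjusted p = 0.565), 0.95 (0.137) and -0.09 (0.781, with a camera test that pointed up). Of 20 clock genes, 1 rose and 7 fell (1 and 8 when adjusted over the list alone), among them Dbp (-0.92, SE 0.20). The list median was -0.71 (camera adjusted p = 0.000429, adjusted p = 0.157 with an estimated correlation). Of 81 nuclear genes of oxidative phosphorylation, 11 fell (13 when adjusted over the list alone), among them Ndufa6 (-1.01, SE 0.21), with a median of -0.39 and a camera adjusted p of 2e-08 (adjusted p = 0.438 with an estimated correlation). Mitochondrial genes took 35.1% of the ANG8 counts and 27.1% of the Ad_GFP counts. Of 27 acute phase genes, 1 rose and 7 fell (1 and 11 when adjusted over the list alone), among them Saa4 (-1.11, SE 0.18), with a median of -0.43 and a camera adjusted p of 0.00128 (adjusted p = 0.374 with an estimated correlation and 0.239 with the mitochondrial share as a covariate). Xenobiotic metabolism genes (31 tested, 1 up and 5 down, 1 and 6 when adjusted over the list alone) had a median of -0.15, a mean of 0.24 and a camera adjusted p of 0.442, and the dioxin-responsive Cyp1a1 rose (2.19, SE 0.37).

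Autophagy and lysosome genes (27 tested, 3 up and 3 down, also when adjusted over the list alone) had a median of -0.04 while the camera test pointed up (adjusted p = 0.969). Within it there was a fall of the autophagy kinase Ulk1 (-1.28, SE 0.24) and a rise of the lysosomal sterol carrier Npc2 (1.00, SE 0.23). Cytosolic ribosomal protein genes (84 tested, 2 up and 1 down, 1 and 1 when adjusted over the list alone) had a median of 0.07 and a camera adjusted p of 0.318. Erythroid genes (7 tested, 0 called by edgeR, also 0 when adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 by DESeq2 and 2 by voom) had a median of 1.02 while the camera test pointed down (adjusted p = 0.880). Of the 3 tested genes of pancreas and adipose tissue, Car3, a carbonic anhydrase also abundant in liver, fell (log2 fold change -1.12, SE 0.20, adjusted p = 0.00204; 1 down also when adjusted over the list alone). The list had a median of 0.64 and a camera test that pointed down (adjusted p = 0.311). In the overexpression comparison camera called 21 of the 34 lists, 9 up and 12 down, and the de novo lipogenesis list was the 1 list called with an estimated correlation, while fry called 19.

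**Figure D2:**
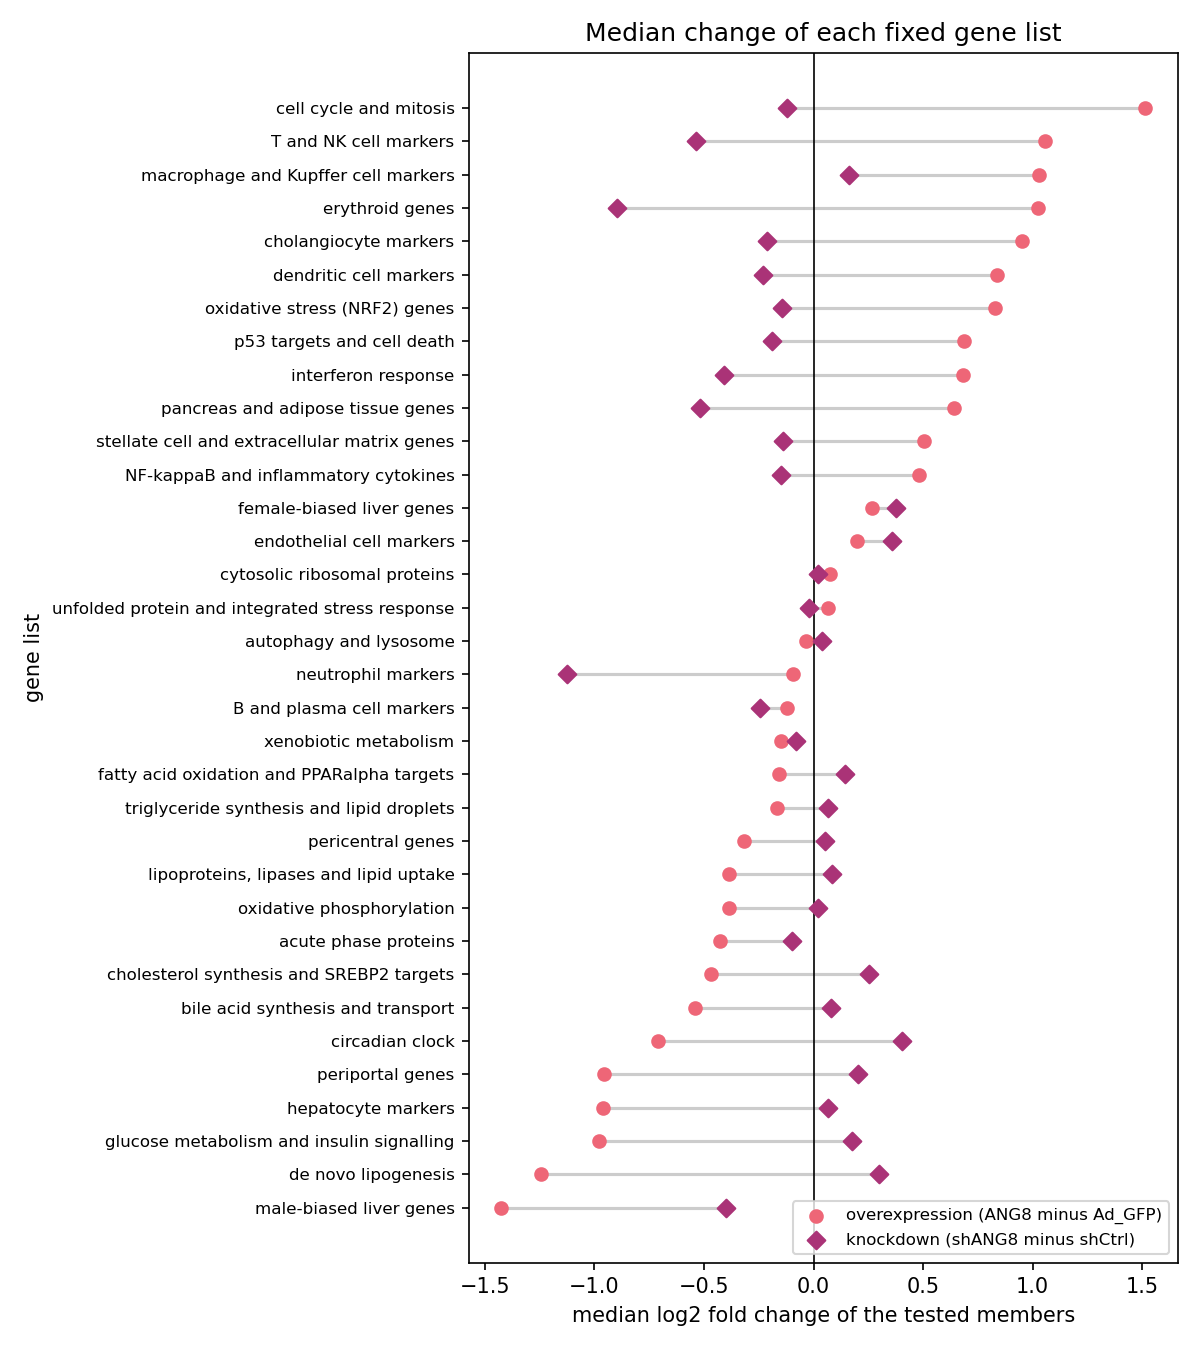
Median log2 fold change (horizontal axis) of the tested members of each of the 34 gene lists (vertical axis), with circles for overexpression (ANG8 minus Ad_GFP) and diamonds for knockdown (shANG8 minus shCtrl). Under overexpression the medians run from -1.42 for male-biased genes to 1.51 for cell cycle genes, and under knockdown the de novo lipogenesis median was 0.30 and the interferon median -0.41.

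The knockdown comparison asked which transcripts differ between shANG8 and shCtrl. Of the 28 called genes, 1 was a ribosomal protein gene and 16 were near-identical copies of such genes. Ctsw, a protease of cytotoxic T cells and NK cells (ENSMUSG00000024910), fell from 7.75 to 3.28 CPM (log2 fold change -1.24, SE 0.23, n = 3 and 3, adjusted p = 0.0334). Ndufb2, a subunit of respiratory complex I (ENSMUSG00000002416), fell from 20.7 to 10.01 CPM (-1.05, SE 0.20, adjusted p = 0.0386). Slfn4, an interferon-inducible gene of myeloid cells, fell from 13.0 to 5.15 CPM (-1.33, SE 0.25, adjusted p = 0.0335), and Cyp2d40, a cytochrome P450 gene, rose from 45.7 to 91.4 CPM (1.00, SE 0.18, adjusted p = 0.0284). Slfn4 and Cyp2d40 have near-identical copies and are uncertain. Calls for Rpl10-ps3 (-4.26), BC002163 (-4.08), Rpl24 (-2.91), Rpl35a-ps2 (-2.85), Rps12-ps4 (-2.60), Rps13-ps2 (-2.13), Rps10-ps1 (-1.48) and Rpl14-ps1 (1.24) are likewise uncertain. In all, 28 of 14686 genes changed, 9 up and 19 down, all by at least 2-fold, and 1164 had an unadjusted p under 0.05. By annotation, 10 were protein-coding, 17 pseudogenes and 1 another kind, and 24 of the 28 had a near-identical copy. When only protein-coding genes without a near-identical copy were tested, edgeR called 0 of 10443 genes (774 at an unadjusted p under 0.05), while DESeq2 called 102 genes of the whole set, limma voom 29 and edgeR without the low-count filter 132. Ctsw lost its call without shCtrl replicate 2 (adjusted p = 0.218), shCtrl replicate 3 (0.0874), shANG8 replicate 1 (0.140) or shANG8 replicate 2 (0.0924), within 0.000591 to 0.218 over its alternatives. Each of the 6 libraries, when left out, ended at least 1 call among Ctsw, Ndufb2, Slfn4, Cyp2d40, Rps10-ps1 and the pseudogene Gm10335. Ctsw and Ndufb2 passed in 10 and 9 of 17 alternatives, and Slfn4, Cyp2d40, Rps10-ps1 and Gm10335 in 9, 11, 11 and 8 of 16. The highest adjusted p was 0.181 for Ndufb2 (without shCtrl replicate 3) and 0.206 for Slfn4 (voom), and without shCtrl replicate 1 it was 0.230 for Cyp2d40, 0.15 for Rps10-ps1 and 0.25 for Gm10335. With all libraries kept, voom ended the calls of Ctsw (adjusted p = 0.100), Ndufb2 (0.0653) and Slfn4, and the fit on the compared groups alone those of Ctsw (0.189), Ndufb2 (0.132), Rps10-ps1 (0.0929) and Gm10335 (0.0929). Ctsw and Ndufb2 also lost theirs on protein-coding genes without a near-identical copy (0.177 for both), Slfn4 and Gm10335 with a stricter low-count filter (just over 0.05 and 0.0581) and Gm10335 with upper quartile normalization (0.0548).

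The lipogenesis, glucose, interferon, NF-kB and T and NK lists had medians of the opposite sign to those under overexpression. EdgeR called 0 members of each when adjusted over all genes. The 23 lipogenesis genes had a median log2 fold change of 0.30 under knockdown, 20 of them positive. EdgeR, DESeq2 and voom called 0 of them, as did edgeR adjusted over the list alone, and 2 had an unadjusted p under 0.05 in edgeR (camera adjusted p = 0.00183, adjusted p = 0.389 with an estimated correlation). Pklr was 0.62 (SE 0.26, adjusted p = 0.556) and Acacb 0.35 (SE 0.17, adjusted p = 0.647). Glucose metabolism genes had a median of 0.17 (camera adjusted p = 0.00331, adjusted p = 0.527 with an estimated correlation), with Khk, the fructose kinase, at 0.86 (SE 0.19, adjusted p = 0.111) called when adjusted over the list alone. The 37 interferon-stimulated genes had a median of -0.41 and 14 members down when adjusted over the list alone (camera adjusted p = 6.66e-13, adjusted p = 0.203 with an estimated correlation). Among them were Psmb9 at -0.75 (SE 0.19, adjusted p = 0.182), Rsad2 at -0.89 (SE 0.25, adjusted p = 0.251) and Zbp1 at -0.65 (SE 0.20, adjusted p = 0.334). The T cell and NK cell list had a median of -0.54 and 1 member down when adjusted over the list alone (camera adjusted p = 3.41e-08, adjusted p = 0.203 with an estimated correlation). Its members included Cd8a at -0.80 (SE 0.19, adjusted p = 0.160) and Gzma at -1.02 (SE 0.40, adjusted p = 0.524). Neutrophil genes had a median of -1.13 and 4 of 5 members down when adjusted over the list alone (camera adjusted p = 2.84e-05, adjusted p = 0.203 with an estimated correlation). NF-kB and cytokine genes had a median of -0.15 and 3 members down when adjusted over the list alone (camera adjusted p = 0.00556, adjusted p = 0.230 with an estimated correlation). DESeq2 called Cd8a (adjusted p = 0.0334), Psmb9 (0.0311) and Khk (0.000994), as did edgeR without the low-count filter, and Zbp1 passed without shANG8 replicate 3 (0.0292). Over all alternatives the adjusted p ran from 0.0334 to 0.373 for Cd8a, 0.0204 to 0.492 for Psmb9, 0.000994 to 0.445 for Khk and 0.0292 to 0.705 for Zbp1.

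Among the remaining lists, camera called the male-biased genes down (median -0.40, 4 called when adjusted over the list alone, adjusted p = 2.84e-05) and the cell cycle genes down (median -0.12, adjusted p = 0.0148), where the adjusted p was 0.389 and 0.865 with an estimated correlation. It called cholesterol synthesis (median 0.25, adjusted p = 0.0148), endothelial genes (0.36, adjusted p = 0.00715), periportal genes (0.20, adjusted p = 0.028) and clock genes (0.40, adjusted p = 0.00154) up, with adjusted p = 0.865, 0.691, 0.736 and 0.389 with an estimated correlation. The members called over all genes, Ndufb2 of oxidative phosphorylation and Rpl24 of the cytosolic ribosomal list, belong to lists that camera did not call, as do the macrophage genes (median 0.16, adjusted p = 0.271) and the hepatocyte genes (median 0.07, adjusted p = 0.344). Signs differed within the lists of triglyceride synthesis (median 0.06, mean -0.02), cytosolic ribosomal proteins (median 0.02, mean -0.01), pancreas and adipose tissue (median -0.52, mean 0.10) and female-biased genes (median 0.38, camera test down, adjusted p = 0.822). In the knockdown comparison camera called 12 of the 34 lists, while an estimated correlation and fry each called 0.

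**Figure D3:**
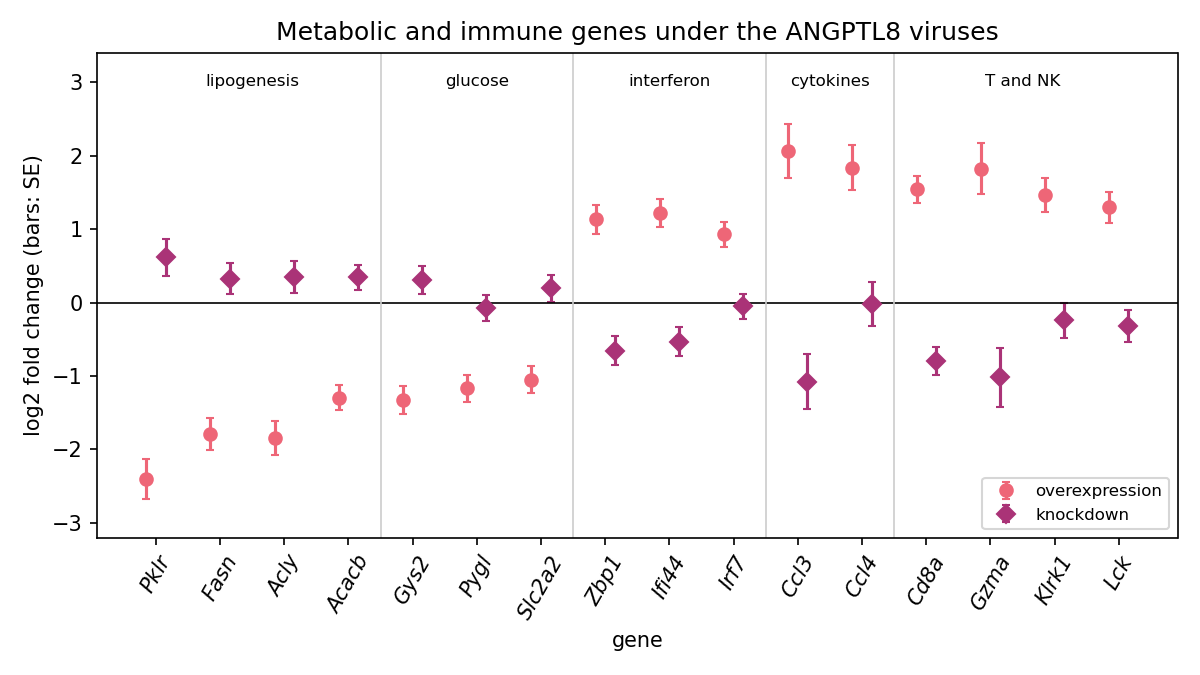
Log2 fold change with SE bars (vertical axis) of 16 genes from the lipogenesis, glucose, interferon, cytokine and T and NK lists (horizontal axis), with circles for overexpression and diamonds for knockdown. Pklr was -2.40 under overexpression and 0.62 under knockdown, and Cd8a was 1.54 and -0.80; each circle passed the test at an adjusted p under 0.05 and no diamond did.

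The difference between the overexpression and knockdown effects asked which genes responded unequally to both ANGPTL8 viruses, each against its own control. Hk3, a hexokinase of white blood cells, had effects of 1.65 (SE 0.18) and -0.68, a difference of 2.33 (adjusted p = 0.000311), and Cd8a had a difference of 2.34 (adjusted p = 0.000509). Macrod1, a mitochondrial hydrolase of ADP-ribose marks, had effects of -1.41 and 0.78, a difference of -2.19 (adjusted p = 0.000878). Cyp2d40 (-2.87, adjusted p = 6.53e-05) and Serpina3g (1.88, adjusted p = 0.000789) also differed, but are uncertain because of near-identical copies. In all, 972 genes differed, 546 higher and 426 lower under overexpression, and 3221 had an unadjusted p under 0.05. A large effect in either comparison alone can also make the difference pass, so these genes did not all move to opposite sides. Abcc4, Lipc and Fasn, for example, passed both the difference and the sum in all 22 alternatives. With an estimated correlation 4 lists passed, among them lipogenesis (median difference -1.44, 12 of 23 lower and 17 when adjusted over the list alone, adjusted p = 0.0203) and T and NK cells (1.67, 13 of 30 higher and 21 when adjusted over the list alone, adjusted p = 0.0214). The others were interferon (1.13, 19 of 37 higher and 32 when adjusted over the list alone, adjusted p = 0.0344) and NF-kB and cytokines (0.74, 5 of 25 higher and 8 when adjusted over the list alone, adjusted p = 0.0344). Glucose metabolism (-1.10, 10 of 28 lower and 17 when adjusted over the list alone) had an adjusted p of 0.0565 with an estimated correlation. Of the 1978 genes changed under overexpression, 1231 (62.2%) had the opposite sign under knockdown and 851 (43.0%) passed the test of the difference. Across all tested genes, which are not independent replicates, the log2 fold changes of both comparisons had a Pearson correlation of -0.0552 and a Spearman correlation of -0.123. The count of 972 moved by over 1.5 times without Ad_GFP replicate 1 (592), Ad_GFP replicate 2 (623), ANG8 replicate 1 (473), shCtrl replicate 1 (487) or shCtrl replicate 2 (578), without the filter on low counts (1510), with DESeq2 (1541) and with voom (1700).

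Of the 22 genes called to the same side in both comparisons, 1 was a ribosomal RNA gene, 1 a ribosomal protein gene and 16 near-identical copies of such protein genes. CT010467.1, an annotated ribosomal RNA gene (ENSMUSG00000106106), held 288 CPM in Ad_GFP, 1538 in ANG8, 438 in shCtrl and 1777 in shANG8, a rise of 2.42 (SE 0.26, adjusted p = 5.36e-05) under overexpression and 2.02 (SE 0.26, adjusted p = 0.000822) under knockdown. BC002163 fell by 3.5 (SE 0.36) and by 4.08 (SE 0.39) on the log2 scale, Rpl10-ps3 fell by 3.42 (SE 0.39) and by 4.26 (SE 0.42), and Rpl24 fell by 2.28 (SE 0.33) and by 2.91 (SE 0.35), all uncertain for their near-identical copies. Ndufb2, which has no such copy, fell by 1.36 (SE 0.20) and by 1.05 (SE 0.20). In all, 8 genes rose in both comparisons, where 0.637 were expected from independent lists (Fisher's exact p = 5.2e-09), and 14 fell in both (1.21 expected, Fisher's exact p = 1.47e-13). Fisher's test takes genes as independent, but 16 of these 22 are near-identical copies of ribosomal protein genes. Copies that share reads do not count independently, so these p-values may be far too small. Ctsw rose under overexpression (0.92, SE 0.22, adjusted p = 0.0104) and fell under knockdown, and Cyp2d40 fell under overexpression (-1.87, SE 0.19, adjusted p = 4.39e-05) and rose under knockdown. They were the 1 gene of each opposite direction, against 1.35 and 0.575 expected (Fisher's exact p = 1 and 0.448). The 22 genes to the same side and 2 to opposite sides were 55 and 32 without the low-count filter, 46 and 15 with DESeq2, and 0 and 0 by edgeR on protein-coding genes without a near-identical copy. The sum of both effects passed for 453 genes, 224 up and 229 down, led by BC002163 (-7.57, adjusted p = 9.69e-07), Rpl10-ps3 (-7.68), Rpl24 (-5.19), Rpl35a-ps2 (-4.55) and Rps13-ps2 (-4.23). A large effect in either comparison alone can also make the sum pass, so these genes did not all move alike. Pklr, which fell under overexpression and not under knockdown, passed the sum in 20 of 22 alternatives. Of the 453 genes, 370 were protein-coding, 64 pseudogenes and 19 of other kinds. That count fell to 181 without ANG8 replicate 1, 292 without ANG8 replicate 2, 245 without Ad_GFP replicate 1, 272 without Ad_GFP replicate 2 and 275 without shCtrl replicate 1. It was 171 without shCtrl replicate 2, 227 without shCtrl replicate 3 and 268 without shANG8 replicate 3, and 984 without the low-count filter, 873 with DESeq2 and 1032 with voom. The lists called with a summed effect were 19 by camera, 0 with an estimated correlation and 7 by fry.

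**Figure D4:**
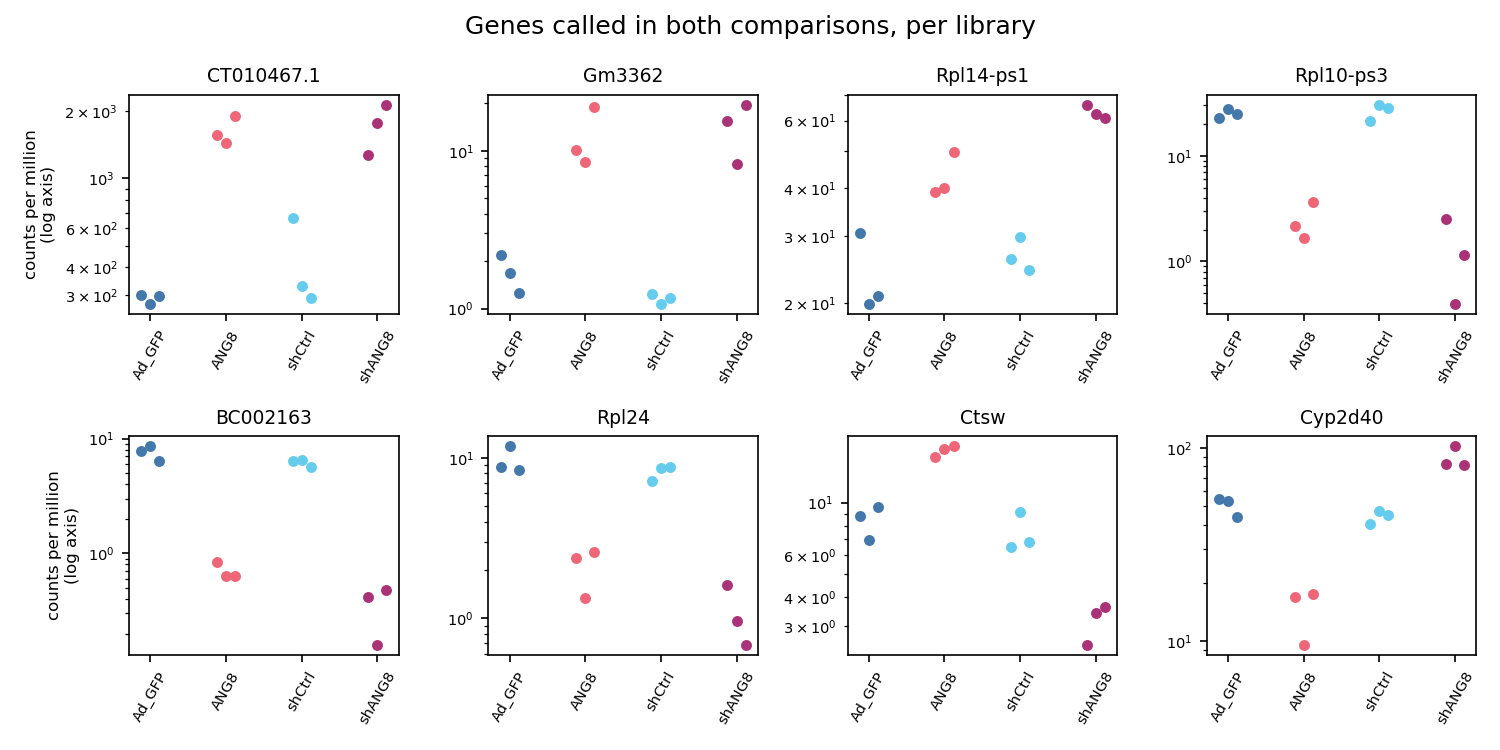
CPM of raw totals (vertical log axes) in each library of the 4 groups (horizontal axes) for 8 genes called in both comparisons; each point is 1 library. CT010467.1 lay higher in the ANG8 and shANG8 libraries than in both controls, while Rpl10-ps3, BC002163 and Rpl24 lay lower there, and Ctsw and Cyp2d40 moved in opposite directions in both comparisons.

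The control viruses were compared to see how far the reference groups differ. Angptl8 had the values given above, 299 CPM in shCtrl and 89.1 CPM in Ad_GFP. Lipogenesis genes had a median log2 fold change of 0.18 in shCtrl minus Ad_GFP, with a camera adjusted p of 0.0147 and an adjusted p of 0.640 with an estimated correlation. EdgeR called 0 of 14686 genes, while 1286 had an unadjusted p under 0.05, DESeq2 called 46 and limma voom 467. Without Ad_GFP replicate 1 the count was 10 and without shCtrl replicate 3 it was 1, the latter being a fit in which Angptl8 passed. Camera called 19 of the 34 lists in this comparison of controls, and an estimated correlation and fry each called 0.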

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

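Of the tests below, all 3 on the ribosomal pseudogenes and the test of a shared shift as the whole cause of the overexpression pattern were chosen only after the results they bear on were seen. The results listed first were picked because the test of the difference between the overexpression and the knockdown effects passed, for single genes in edgeR and for gene lists in camera with an estimated correlation. That test passed for 972 genes. Of 100 splits of the libraries within both arms, 2 gave as many genes, the real one included, with 1087 in the highest other split, and for the 453 genes of the sum 3 of 100 gave as many, again with 1087 in the highest other. Both shares lay under 0.05, the bound set beforehand. These splits shuffle both arms at once, so they speak only against chance in both arms together and not in either arm. The splits that reached these counts kept the real ANG8 and Ad_GFP groups and shuffled the knockdown arm alone. Chance is thus not excluded for the grouping of the knockdown libraries, and both counts rest mainly on the overexpression arm. That arm alone has 10 splits, too few for a share under 0.05.

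Values are differences of log2 fold changes, overexpression minus knockdown, and a large value can come from the overexpression effect alone. Angptl8 itself differed by 2.58. Among metabolic genes the difference was -3.02 for Pklr, -2.12 for Fasn, -2.19 for Acly, -1.64 for Acacb, -1.15 for Dgat2, -1.40 for Stard4, 1.31 for Ucp2, -1.92 for Lipc, 1.77 for Lpl, 1.93 for Abcg1, -2.24 for Slc10a1, -1.67 for Slc27a5, -1.63 for Gys2, -1.10 for Pygl, -1.24 for Slc2a2 and -1.77 for Khk. Among hepatocyte, zonal, sex-biased and acute phase genes it was -2.10 for Hpd, -1.71 for Uox, -1.87 for Gls2, -1.96 for Hal, -1.38 for Cps1, -1.32 for Cyp2c29, -2.54 for Slco1a1, -3.79 for Mup19, -3.39 for Slc22a28, -4.89 for Igfbp2, -2.87 for Cyp2d40, -0.85 for Saa4 and 2.21 for Cyp1a1. Among interferon and cytokine genes it was 1.75 for Ifi44, 1.79 for Zbp1, 0.98 for Irf7, 1.32 for Psmb9, 1.93 for Rsad2, 3.43 for Ubd, 1.97 for Slfn4, 3.14 for Ccl3, 1.86 for Ccl4 and 2.35 for Ccl24. Among lymphocyte and macrophage genes it was 2.34 for Cd8a, 1.71 for Klrk1, 1.61 for Lck, 2.84 for Gzma, 2.16 for Ctsw, 3.15 for Pdcd1, 2.33 for Hk3, 1.88 for Serpina3g, 1.51 for Aif1, 1.49 for Cd5l, 1.92 for Spic, 2.01 for Cd74 and 1.59 for H2-Aa. For the remaining genes it was 4.05 for Abcc4, 3.88 for Srxn1, 2.55 for Slc1a4, 2.63 for Ksr2, -2.19 for Macrod1, 1.42 for Vim, 1.67 for Gsr, 2.54 for Gclc, 1.45 for Txnrd1, 2.26 for Top2a, 2.56 for Ccne1, 1.67 for Mki67, 1.43 for Ccng1, 1.54 for Casp1, -1.39 for Dbp, -1.13 for Ndufa6 and -1.30 for Ulk1. The median difference was -1.44 for the lipogenesis list, 1.13 for interferon, 0.74 for NF-kB and cytokines and 1.67 for T and NK cells. Lpl, Mup19, Slc22a28, Cyp2d40, Slfn4, Serpina3g and Mki67 have near-identical copies by a rule that a partial match can meet, and are marked uncertain. Of the 71 named genes called in the difference, 52 were called under every alternative that tested them. Saa4 passed in 7 of 22 alternatives, H2-Aa and Ubd in 12 of 22 and Slc22a28 in 12 of 21. Slco1a1, Stard4 and Vim passed in 14 of 22.

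In the first pattern, 22 genes called in both comparisons, of which 1 was a ribosomal RNA gene, 1 a ribosomal protein gene and 16 near-identical copies of such protein genes, moved to the same side under the overexpression and the knockdown virus, against 2 that moved to opposite sides. These numbers were 55 and 32 without the filter on low counts, 46 and 15 with DESeq2, and 0 and 0 by edgeR on protein-coding genes without a near-identical copy. The measured Angptl8 level moved to opposite sides in the same comparisons. Its counts may not measure the transgene, however, and its lower level under knockdown did not pass when adjusted over all genes. Of the 28 knockdown genes, 82.1% (23) had the same sign under overexpression. The 22 genes of the pattern are among these 28, so this share restates the pattern and is no separate evidence on its cause. A gene that simply followed the measured Angptl8 level would have moved to opposite sides, and these 22 did not. Reads shared between near-identical copies stay open as a part: 85.7% of the 28 genes had such a copy against 21.1% of 14650 other genes, but this explanation was drawn from the same genes, copies that share reads do not count independently, and sharing alone does not make groups differ. Preparation or sequencing of the ANG8 and shANG8 libraries apart from both control groups cannot be told apart from the virus itself, since no label gives a library batch. The median absolute log2 difference within a kind of virus was 0.155 of that between kinds, but the genes were picked for a difference between kinds, so this ratio decides nothing. A response of the liver to any ANGPTL8 virus stays open and was not tested, and for the 28 genes the 10 splits of 6 libraries (1 with as many, highest other 0) are too few for a share under 0.05.

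The second pattern is the overexpression programme, with lower hepatocyte, lipogenic and glucose genes and higher interferon, T and NK cell, macrophage and cell cycle genes. With an estimated correlation, of these lists only lipogenesis stayed called, and the others had adjusted p of 0.0608 (T and NK cells) to 0.113 (cell cycle). A loss of hepatocytes with all other cell types in fixed proportion would raise markers of those types alike. The macrophage list rose by 0.931 (SE 0.0979) more than the endothelial list, which argues against such a loss as the whole cause. The test cannot decide on a lower hepatocyte share that comes with more immune cells, since endothelial markers need not rise then. With the mitochondrial share as a covariate, 77.1% of the 1978 genes (1525) kept their call and direction, which argues against that share as the whole cause. For an influence shared by both ANGPTL8 viruses, the test set beforehand met neither of its bounds. Of the 1978 genes, 43.0% passed the test of the difference. Their mean change in the direction taken under overexpression was 1.20 (SE 0.0857) there and -0.0874 (SE 0.0976) under knockdown. The overexpression value is positive by construction and raised by the choice of genes, so it is no evidence by itself. The knockdown value, whose libraries did not set these directions, argues against a shared shift as the whole cause, and a shared part stays open. A hypothesis in line with these values is a response to the ANG8 virus, to the amount of protein made from it or to ANGPTL8, with infiltrating or dividing cells as a possible part, and the design does not separate these. For the 1978 genes the 10 splits of 6 libraries (1 with as many, highest other 0) are too few for a share under 0.05.

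In the third pattern, Angptl8 was higher in shCtrl (299 CPM) than in Ad_GFP (89.1 CPM), although edgeR called 0 genes between these control groups. All 10 of 10 splits gave as many, with a highest other of 0, which is certain for a count of 0 and decides nothing. A more strongly fed or insulin-stimulated state of the shCtrl mice may raise Angptl8 and lipogenic genes together, and the lipogenesis list was higher in shCtrl, where the camera test across genes gave an unadjusted value of 0.00386 (adjusted p = 0.0147). The unadjusted value was 0.122 with an estimated correlation, camera called 19 of 34 lists in a comparison with 0 called genes, and no label gives the feeding state, so this test does not decide. The fed state and a difference between the control viruses cannot be told apart here.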

How the results depend on the processing

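The added tests with the mitochondrial share as a covariate, without mitochondrial genes, and on protein-coding genes without a near-identical copy were chosen only after the data were seen, and the other alternatives were planned. The overexpression count stayed within 1.5 times of 1978 in every setting that kept all libraries except limma voom, while calls under knockdown, in the difference, in the sum and between controls moved with the tool and the filter. With 3 libraries a group and 12537083 to 15144312 counts a library, most 1.5-fold changes were missed in simulated data with few changed genes. The share recovered was 4.48% in the overexpression draw, so an uncalled gene is not shown to be unchanged. Except where fewer genes or libraries were used, the cause was not tested.

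Without a filter on low counts, 132 genes were called under knockdown, 1510 in the difference, 984 in the sum and 96 between controls, with 55 called in both comparisons to the same side and 32 to opposite sides, and Angptl8 was called under knockdown at -1.33. DESeq2 called 102, 1541, 873 and 46, with 46 and 15 in both, and Angptl8 under knockdown at -1.30. Limma voom called 4181 genes under overexpression, 1700 in the difference, 1032 in the sum and 467 between controls, with 1 to opposite sides, and the fit on the compared groups alone also had 1. With the mitochondrial share as a covariate, Angptl8 lost its overexpression call at 1.08, the knockdown count was 47 and 5 genes went to opposite sides; acute phase lost its call under overexpression (adjusted p = 0.239) while cholangiocyte (0.0464), unfolded protein response (0.0131) and cytosolic ribosomal genes (0.0353) gained it, and under knockdown cholesterol (0.0568) and periportal genes (0.0817) lost theirs and acute phase gained it (0.0110). On protein-coding genes without a near-identical copy, fewer genes were tested, with 0 called by edgeR under knockdown (774 at an unadjusted p under 0.05, against 102 by DESeq2 on all genes), 251 in the sum, and 0 in both comparisons to the same or opposite sides.

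With an estimated correlation, the lists called fell from 21 to 1 under overexpression and from 12 to 0 under knockdown. The overexpression lists that lost their call had adjusted p of 0.411 (cholesterol), 0.182 (lipoproteins), 0.0608 (bile acids, NF-kB, T and NK cells, p53), 0.0665 (glucose, interferon, macrophage, male-biased), 0.374 (acute phase), 0.108 (dendritic), 0.630 (stellate), 0.0857 (hepatocyte), 0.177 (pericentral), 0.0780 (periportal), 0.140 (NRF2), 0.113 (cell cycle), 0.157 (clock) and 0.438 (oxidative phosphorylation). Those under knockdown had 0.389 (lipogenesis, male-biased, clock), 0.865 (cholesterol, cell cycle), 0.527 (glucose), 0.203 (interferon, T and NK cells, neutrophil), 0.230 (NF-kB), 0.691 (endothelial) and 0.736 (periportal). Fry, which asks another question, called 19 lists under overexpression, without cholesterol (0.0885), acute phase (0.0748), stellate (0.251) and oxidative phosphorylation genes (0.0748) and with cholangiocyte (0.0418) and pancreas and adipose genes (0.00394). It called 0 under knockdown: lipogenesis, male-biased and clock 0.243, cholesterol and cell cycle 0.796, glucose 0.344, interferon and NF-kB 0.0897, T and NK cells 0.0703, neutrophil 0.110, endothelial 0.502 and periportal 0.559.

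Leaving out 1 library at a time, with fewer samples, gave 995 to 1684 genes under overexpression, 473 to 1227 in the difference, 171 to 603 in the sum, 0 to 10 between controls and 0 to 13 to opposite sides in both comparisons. Angptl8 ranged from 0.93 to 1.45 under overexpression and from -1.59 to -1.06 under knockdown. List adjusted p under overexpression ranged from 0.00741 to 0.233 for fatty acid oxidation, 0.000221 to 0.307 for stellate, 0.0194 to 0.959 for unfolded protein response, 0.0296 to 0.878 for cytosolic ribosomal and 0.000672 to 0.945 for erythroid genes. Under knockdown they ranged from 3.73e-06 to 0.0816 for lipogenesis, 4.84e-07 to 0.551 for cholesterol (reversed without shANG8 replicate 1), 0.00147 to 0.677 for fatty acid oxidation, 4.08e-06 to 0.116 for glucose, 0.00124 to 0.116 for NF-kB, 0.00533 to 0.843 for acute phase, 0.000121 to 0.623 for macrophage, 0.0101 to 0.725 for dendritic, 0.0002 to 0.438 for endothelial, 0.00774 to 0.846 for hepatocyte, 0.0471 to 0.668 for pericentral, 0.00021 to 0.562 for periportal, 6.24e-05 to 0.974 for xenobiotic, 0.00325 to 0.757 for NRF2, 9.51e-17 to 0.844 for cell cycle, 0.00212 to 0.655 for p53, 3.73e-06 to 0.0696 for clock and 0.0292 to 0.934 for oxidative phosphorylation genes. In the difference the xenobiotic list ranged from 0.0436 (reversed, without shANG8 replicate 3) to 0.922. Among results of named genes, none reversed: 1995 held, 355 lost and 2 gained a call when 1 library was left out, and 2589 held, 56 lost and 12 gained one in other settings.

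The replicate block took the replicate number as a term in each arm. It called 2301 genes under overexpression, 52 under knockdown, 1387 in the difference, 724 in the sum and 8 between controls. Each count was above that without the block. In that fit 6 genes went to opposite sides, Angptl8 passed under knockdown at -1.26 and the p53 list passed there (adjusted p = 0.0483). Correlations of same-numbered libraries' deviations were -0.0667, 0.116 and 0.149 in the overexpression arm and 0.0345, 0.0824 and 0.186 in the knockdown arm. These low values do not settle whether the numbers pair the samples. Replicates 2 and 3 correlated best with their own number in each arm and replicate 1 did not.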

Other observations

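Tests of Cd226 and Gm3788 in this part were chosen only after their values were seen, while those of the other genes and of the lists were planned. Cd226, an activating receptor of T cells and NK cells (ENSMUSG00000034028), had 0 counts in each of the 3 shANG8 libraries and 16 to 26 counts in each of the other 9. The shCtrl libraries held 51 counts together, Ad_GFP 62 and ANG8 59. With a floor of 3 counts over the shANG8 group, shANG8 was at least 16-fold lower than the observed shCtrl level. That bound covers counting error in shANG8 alone, not that in shCtrl or the spread between libraries. The knockdown call of Cd226 by edgeR (adjusted p = 0.00863) was lost with limma voom (0.0653), in the fit on the compared groups alone (0.0801) and on protein-coding genes without a near-identical copy (0.116), within 5.12e-05 to 0.116 over its alternatives. The pseudogene Gm3788, which has a near-identical copy, had 4, 0 and 1 counts in shANG8 and 30 to 41 in shCtrl.

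Under overexpression a few genes ran against or beside their lists, and Slc2a4, which is not in the glucose list, also changed. Fitm1, a lipid droplet gene, rose (log2 fold change 0.99, SE 0.28, adjusted p = 0.0298) while Dgat2, an enzyme of triglyceride synthesis, fell (-0.74, SE 0.19, adjusted p = 0.0172), and both lost their calls when single libraries were left out, most without Ad_GFP replicate 1 for Fitm1 (adjusted p = 0.121, range 1.55e-05 to 0.121 over its alternatives) and without Ad_GFP replicate 2 for Dgat2 (0.0719, range 0.00141 to 0.0719). Atf3, a stress-induced transcription factor, rose (1.58, SE 0.41, adjusted p = 0.0187) while Xbp1, a regulator of the unfolded protein response, fell (-0.86, SE 0.20, adjusted p = 0.0101). Atf3 lost its call without ANG8 replicate 3 (0.0528, range 1.51e-06 to 0.0528) and Xbp1 lost it without Ad_GFP replicate 1 (0.0569) or ANG8 replicate 1 (0.0648, range 6.43e-05 to 0.0648). Slc2a4, the insulin-responsive glucose transporter, fell from 17.5 to 1.73 CPM (-3.37, SE 0.81, adjusted p = 0.0218), but did not pass without Ad_GFP replicate 2 (0.0622), ANG8 replicate 1 (0.0818) or ANG8 replicate 3 (0.0536), nor without the filter on low counts (0.0565), within 7.06e-05 to 0.0818 over its 17 alternatives. Il1rn, the interleukin 1 receptor antagonist, rose (1.12, SE 0.29, adjusted p = 0.0183), but did not pass without Ad_GFP replicate 1 (0.0595), Ad_GFP replicate 2 (0.0707) or ANG8 replicate 1 (0.0798), within 0.000222 to 0.0798 over its 17 alternatives.

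The neutrophil list had a median of -1.13 under knockdown and -0.09 under overexpression, and endothelial genes had medians of 0.36 and 0.20. Clock genes had medians of -0.71 under overexpression and 0.40 under knockdown, and the time of day of collection is not given in the sources used here. Of the 1978 genes called under overexpression, 1814 were protein-coding, 71 pseudogenes and 93 of other kinds, against 10, 17 and 1 of the 28 called under knockdown.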
